A study of Rattus norvegicus with 9 samples.

How the data were processed

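The data are 9 single-channel Affymetrix rat expression arrays of the hypothalamus of female rats, with 3 arrays each of juvenile animals (day 26), early pubertal animals (day 29) and late pubertal animals (day 31). Groups, ages and replicate numbers came from the sample titles and source names. Per the labels' protocols, tissue was stored in RNAlater, total RNA was purified on RNeasy columns, and biotin-labelled cRNA was made by in vitro transcription from cDNA primed with oligo-dT. The deposited values are signal intensities per probe set on a linear scale, which the authors made with the MAS5 algorithm, per the submitters' processing notes. Its version, target level and masks are not given in the sources used here. The labels give no batch, date or pairing, so none was modelled.

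The deposited intensities had been expected to share a common level between arrays and did not. Their trimmed means, leaving out 2% at each end, differed by up to 1.41 times between arrays. Values were therefore taken as log2(signal + 16) and quantile-normalized between arrays. This departs from the planned analysis at the level as deposited, was decided before any test was run, and the deposited level is reported beside it. Fold changes are on the log2(signal + 16) scale and understate the change of dim probe sets. Median signal per array was 113, 108 and 102 in juvenile replicates 1, 2 and 3, 101, 91.7 and 79.8 in early pubertal replicates 7, 8 and 10, and 102, 102 and 122 in late pubertal replicates 12, 14 and 20.

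The table held 31099 probe sets, of which 57 controls were left out. Of the other 31042 probe sets, 20826 have 1 gene symbol in the platform annotation, 436 have several and 9780 are unnamed here, and 20758 matched a current gene record through their Entrez identifier, which changed 0 symbols. Only probe sets with 1 symbol were named. Probe sets were kept where their mean over the 9 arrays lay above the 40th percentile, leaving 18625, of which 14268 carry 1 symbol and stand for 10600 genes.

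Differences were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per stage over all 9 arrays, an empirical Bayes prior with an intensity trend (5.80 prior and 6 residual degrees of freedom), two-sided tests and Benjamini-Hochberg adjustment over probe sets at a threshold of 0.05. The 3 pairwise differences between stages and a moderated F test over all stages were computed. Differences are log2 with the SE of the fit. P-values were adjusted within each comparison, not over the 3 of them.

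Gene lists were tested with camera in limma at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists, and again with the correlation estimated from the data. Fry, which tests whether a list's genes move on balance in a single direction, was an alternative. Each gene was represented by its brightest tested probe set. There were 31 lists holding 725 entries, of which 619 matched a named gene, and 30 lists had the minimum of 5 tested genes. Markers of red blood cells had 3 tested genes of 7 named and were not tested. The lists covered peptides and regulators of puberty, transmitter signalling, immediate early, clock, glucocorticoid-responsive, stress and metabolic genes, and markers of the cell types, neighbouring tissues and membranes that a dissected hypothalamus can hold. A list shift is the mean log2 difference of its members minus that of the other tested genes. A list score per array is the mean deviation of the members from their average over all arrays, less that of all tested genes. Scores were compared by exact permutation over the 280 ways to split the arrays into 3 groups of 3. The 2 differences from juvenile animals share the juvenile arrays, so their correlation was set beside that of 100 simulated pairs of unchanged groups.

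The comparisons, tests, gene lists, named-gene rule and alternatives were fixed before the data were examined, except for the normalization above and the tests and alternatives named below. Named genes were, per comparison and direction, up to 10 with the largest difference among those past the threshold with non-overlapping stages, filled up to 5 by the smallest unadjusted p among non-overlapping genes where fewer than 10 passed. The rule added up to 5 genes per direction by the F test, up to 4 members of each list with the smallest p, and every member of the GnRH control and puberty-linked regulator lists. Where probe sets of a named gene went opposite ways, both are given, and other probe sets of the genes named by their p are given beside them.

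The alternatives were constants of 1 and 64 before the log, the deposited level, median centring, no filter and a filter at the 60th percentile, a prior without trend or with robust estimation, array weights, fits on only the 6 arrays compared, a threshold of 0.1, 1 probe set per gene, the mean of a gene's probe sets in lists, and leaving out each array in turn. Exact permutation of list scores, the immediate early list without Fos, lists without genes that other lists hold, the test of clock genes and the correlation among leptomeningeal genes within stages were chosen after seeing the data.

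The steps were tested on simulated data for the comparison of early pubertal with juvenile animals, with 200 of 18625 probe sets changed in each of 10 runs. Limma recovered 47.6% of probe sets changed 1.5-fold, 87.2% of those changed 2-fold, 99% of those changed 3-fold and 100% of those changed 4-fold, with 9.8 false calls among 176.7 calls per run. A list shifted by 0.3 among 10600 genes was called by camera in 10 of 10 runs, and other lists were called 2 times. Simulated noise was independent between genes, which real noise is not. Figures were drawn with matplotlib 3.10.9 and tables joined with pandas 2.3.3 in Python 3.11.15.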

Results

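The hypothalamus of normally developing female rats was profiled on Affymetrix rat expression arrays at 3 stages of sexual maturation. Arrays of juvenile animals at day 26, which the labels name as controls, were set beside arrays of early pubertal animals at day 29 and late pubertal animals at day 31. Each stage had 3 arrays, and the labels give each array the hypothalamus of a single rat, so n = 3 stands for animals. The hypothalamus holds the neurons that release gonadotropin-releasing hormone (GnRH), the peptide that drives the pituitary at puberty, together with the glia and vessels around them.

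The median signal per array was 107 ± 5.36 (SD, n = 3) in juvenile, 90.9 ± 10.7 in early pubertal and 109 ± 11.7 in late pubertal animals. An exact two-sided permutation test of early pubertal against juvenile arrays gave p = 0.1, the smallest value that 3 against 3 can reach, and late pubertal arrays gave an exact p of 0.9. Early pubertal replicate 10 was the dimmest array at 79.8, and late pubertal replicate 20 was the brightest at 122. The 3′ to 5′ signal ratio of the beta-actin control, which rises as RNA degrades, was 2.73 ± 0.388 (SD, n = 3), 2.54 ± 0.367 and 2.78 ± 0.483 in the order of the stages. Its exact permutation p against juvenile was 0.5 for early and 0.9 for late pubertal animals. Arrays correlated with each other across probe sets at r = 0.966 to 0.979, and no pair held identical values. The number of arrays limits the precision of every comparison.

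The comparison of day 29 with day 26 asked which transcripts differ as puberty begins. Akr1c15, an aldo-keto reductase, was 2.57-fold higher in early pubertal animals, a log2 difference of 1.36 ± 0.20 (SE, n = 3 per stage) with a limma adjusted p of 0.310. Its juvenile mean was dim, at a log2 level of 5.88, as was the early pubertal mean of Hhipl1 at 5.97, and no detection calls were used. Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase, stood 0.58 ± 0.13 higher on the log2 scale. Ndrg1, a stress- and differentiation-responsive gene, stood 0.50 ± 0.13 higher and the interferon-inducible Ifi27 0.32 ± 0.07 higher. Fos, an activity-induced transcription factor, had a log2 difference of −1.10 ± 0.24, and Dnajc7, a cochaperone of Hsp70, one of −1.44 ± 0.30 on the named probe set and −0.02 ± 0.10 on its other. Hhipl1 differed by −1.12 ± 0.19, the guanine nucleotide exchange factor Trio by −0.43 ± 0.10 and Dync1li1, a light intermediate chain of cytoplasmic dynein, by −0.39 ± 0.09. By the naming rule, the 3 arrays of each stage did not overlap for any of these genes. Their limma adjusted p ran from 0.310 for Akr1c15 to 0.852 for Hhipl1 and 0.994 for the others. Gpatch4 was 0.70 ± 0.16 higher on the named probe set, while its other 2 probe sets gave −0.09 and −0.11. The other probe sets of Hhipl1 and Trio gave 0.20 and −0.16, and those of Gpd1 and Ndrg1 gave 1.04 and 0.30. None of these genes passed the test on normalized values: limma with Benjamini-Hochberg adjustment called 0 of 18625 probe sets, and 831 had an unadjusted p under 0.05, 357 higher and 474 lower, where chance gives 931. Arrays of the stages were fully separated for 719 higher and 826 lower probe sets, 8.30% of those tested against 10% by chance. Without normalization between arrays, limma called 10 probe sets, 1 higher and 9 lower, beside a median log2 difference of −0.24 over all tested probe sets. The 1 higher was that of Akr1c15 at 1.17 (adjusted p 0.0406), and the named probe sets of Fos (0.00217), Dnajc7 (0.00472) and Hhipl1 (0.0204) were among the 9 lower.

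Gene groups were then tested against the other genes between the same stages. Camera with Benjamini-Hochberg adjustment placed 5 of 30 lists above and 2 below the other tested genes in early pubertal animals, while 0 passed with an estimated correlation and 0 by fry. Without normalization between arrays the split was 5 and 1, and with each array centred on its median it was 7 and 1. In no list did a member pass over all genes on normalized values. Immediate early genes, which neuronal activity induces within minutes, were lower for 14 of 16 tested members, with a mean log2 shift of −0.20 relative to other genes and a camera adjusted p of 0.00141 (adjusted p = 0.212 with an estimated correlation). The estimated correlation of this list was −0.00677, below the preset 0.01, so correlation between members does not explain the lost call. Above the preset lay leptomeninges (0.506), astrocytes (0.151), glucocorticoid-responsive genes (0.114), ribosomal proteins (0.103), choroid plexus (0.0482) and GnRH control (0.0277), all called against juvenile animals. The same cannot be said of those lists. Among immediate early genes, Fos alone passed when adjusted over the list alone, at 0.0123. Egr1 had a difference of −0.44 ± 0.16 and Ier2 one of −0.34 ± 0.15, and Egr3 went the other way at 0.55 ± 0.29. The list kept its call without any single array, at adjusted p up to 0.0346.

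Glucocorticoid-responsive genes were higher for 14 of 16 members, by 0.17 relative to other genes (camera adjusted p 0.00106, and adjusted p = 0.348 with an estimated correlation), with 0 members passing when adjusted over the list alone. Sult1a1 differed by 0.40 ± 0.12, Fkbp5, a cochaperone of the glucocorticoid receptor, by 0.28 ± 0.11, and Arrdc2 by 0.45 ± 0.20. Markers of leptomeninges and fibroblasts, the membranes on the brain surface, were higher for 14 of 15 members, by 0.15 (camera adjusted p 0.00106, and adjusted p = 0.587 with an estimated correlation), with 0 passing when adjusted over the list alone. Among them Mgp differed by 0.36 ± 0.14, Dcn, the proteoglycan decorin, by 0.33 ± 0.15 and the transporter Slc6a13 by 0.46 ± 0.20. Cytosolic ribosomal proteins were higher for 23 of 31 members, by 0.04 (camera adjusted p 0.00106, and adjusted p = 0.410 with an estimated correlation), with Rplp0 at 0.22 ± 0.07 and 0 passing when adjusted over the list alone. All 3 calls rested on early pubertal replicate 10: without that array the glucocorticoid shift was 0.06 (adjusted p 0.152), the leptomeninges shift −0.03 (0.968) and the ribosomal shift 0.03 (0.148), and 1 list in all was called in place of 7. Without early pubertal replicate 7 the leptomeninges shift was 0.22 and the ribosomal shift 0.07, and without replicate 8 the leptomeninges shift was 0.24. Ribosomal proteins shifted by 0.13 with each array centred on its median, and lost the call without normalization between arrays (adjusted p 0.252) and with a variance prior without trend (0.0592).

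Peptides and receptors that control GnRH neurons were higher for 11 of 16 tested members in early pubertal animals, by 0.12 relative to other genes (camera adjusted p 0.0276, and adjusted p = 0.348 with an estimated correlation), with 0 passing when adjusted over the list alone. Neurotensin (Nts) differed by 0.34 ± 0.12, Npvf, which encodes RFamide peptides that inhibit gonadotropin release, by 0.59 ± 0.23, Tac3, which encodes neurokinin B, by 0.36 ± 0.17 and Pdyn, the dynorphin precursor, by 0.24 ± 0.13. The progesterone receptor Pgr had a value of −0.29 ± 0.21. Gnrh1, Kiss1r, Esr1, Esr2 and Pomc lay below the signal filter, and Kiss1 and Agrp are not analysed here. The GnRH list lost its call without juvenile replicate 1 (adjusted p 0.0886), juvenile replicate 2 (0.118), early pubertal replicate 7 (shift 0.08, adjusted p 0.292) or early pubertal replicate 10 (0.0742), with array weights (0.0851) and with a variance prior without trend (0.0680). Its shift was 0.18 with the stricter signal filter.

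Astrocyte markers were higher for 12 of 16 members, by 0.10 (camera adjusted p 0.0208, and adjusted p = 0.555 with an estimated correlation), with Aldh1l1 at 0.33 ± 0.11 and Gfap, the glial filament protein, at 0.16 ± 0.07. Markers of immature neurons were lower for 13 of 18 members, by a mean of −0.08 (camera adjusted p 0.0473, and adjusted p = 0.348 with an estimated correlation). The estimated correlation of the immature neuron list was −0.0376, also below the preset 0.01. The homeobox gene Dlx1 had a difference of −0.33 ± 0.14, Dpysl5 −0.24 ± 0.10 and the semaphorin receptor Nrp1 −0.23 ± 0.10, while Stmn1, a regulator of microtubules, stood at 0.19 ± 0.07. In both lists 0 members passed when adjusted over the list alone. The astrocyte call was lost without juvenile replicate 2 (shift 0.04, adjusted p 0.298), early pubertal replicate 8 (0.04, 0.318) or early pubertal replicate 10 (0.0742), and its shift was 0.15 without early pubertal replicate 7. It was lost as well without normalization between arrays (shift 0.16, adjusted p 0.0645), with array weights (0.0851) and with a variance prior without trend (0.0680). The immature neuron call was lost without juvenile replicate 1 (0.0886) or 3 (shift −0.05, adjusted p 0.353), early pubertal replicate 7 (0.357) or 10 (0.0742), and late pubertal replicate 12 (0.0539), 14 (0.0599) or 20 (0.0504). It was also lost without normalization (0.139), with median centring (0.331), with the stricter filter (0.0911), without trend (0.0592) and with only the 6 arrays compared (0.0628).

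Regulators that the study group has linked to puberty showed no list shift in early pubertal animals, with a mean of −0.03 relative to other genes, 4 of 9 tested members higher and a camera adjusted p of 0.461. Cadm1, a synaptic and glial adhesion molecule, had a value of −0.26 ± 0.09 (SE, n = 3 per stage), and −0.12 on its other probe set, Irf2bpl one of −0.14 ± 0.07 and Cux1 one of 0.09 ± 0.10, with the other Cux1 probe set at −0.19. In late pubertal animals the shift from juvenile was 0.03, with 6 of 9 members higher and a camera adjusted p of 0.972. Cadm1 then stood at −0.16 ± 0.09. Usf2, a bHLH transcription factor, stood at 0.21 ± 0.25, and at −0.000471 without juvenile replicate 2, where its sign turned, and the other Usf2 probe set gave −0.01. No member passed over all genes or when adjusted over the list alone, and this list is not independent evidence because some of its genes may have been chosen on these samples.

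The comparison of day 31 with day 26 asked what differs between the juvenile and the late pubertal hypothalamus. Akr1c15 was 2.55-fold higher in late pubertal animals, a log2 difference of 1.35 ± 0.20 (SE, n = 3 per stage) with a limma adjusted p of 0.336. Meg3, an imprinted long noncoding RNA, stood 0.70 ± 0.11 higher on the named probe set with an adjusted p of 0.371, and 0.07 ± 0.12 on its other. Gpd1 stood 0.68 ± 0.13 higher and Fibin 0.67 ± 0.13 higher, both at an adjusted p of 0.768, and Ndrg1 stood 0.56 ± 0.13 higher. Kazn, which encodes the cell junction protein kazrin, had a difference of −1.04 ± 0.19 (adjusted p 0.733), with its other probe sets at −0.24 and 0.01. Meis2, a homeobox transcription factor, differed by −1.08 ± 0.23, the lipase Pnlip by −0.59 ± 0.12, Dhrs13 by −0.63 ± 0.13 and Insyn1, a protein of inhibitory synapses, by −0.52 ± 0.12. Akr1c15 in juvenile and Meis2 in late pubertal animals were dim, at mean log2 levels of 5.88 and 6.11. The other probe sets of Dhrs13, Insyn1, Gpd1, Fibin and Ndrg1 gave −0.09, −0.32, 0.98, 0.76 and 0.36. By the naming rule, the arrays of both stages did not overlap for these genes. None passed on normalized values: limma with Benjamini-Hochberg adjustment called 0 of 18625 probe sets. An unadjusted limma p under 0.05 was reached by 772, 415 higher and 357 lower. Fully separated probe sets numbered 1099 higher and 1029 lower, 11.4% of those tested against 10% by chance. Without normalization between arrays limma called 1 probe set, that of Akr1c15 at 1.39 (adjusted p 0.0228), beside a median difference of −0.02. With array weights it called the named Meg3 probe set at 0.79 (adjusted p 0.0287), and without juvenile replicate 2 an unnamed probe set at −1.18 (adjusted p 0.0143), chosen here after its value was seen.

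**Figure D1:**
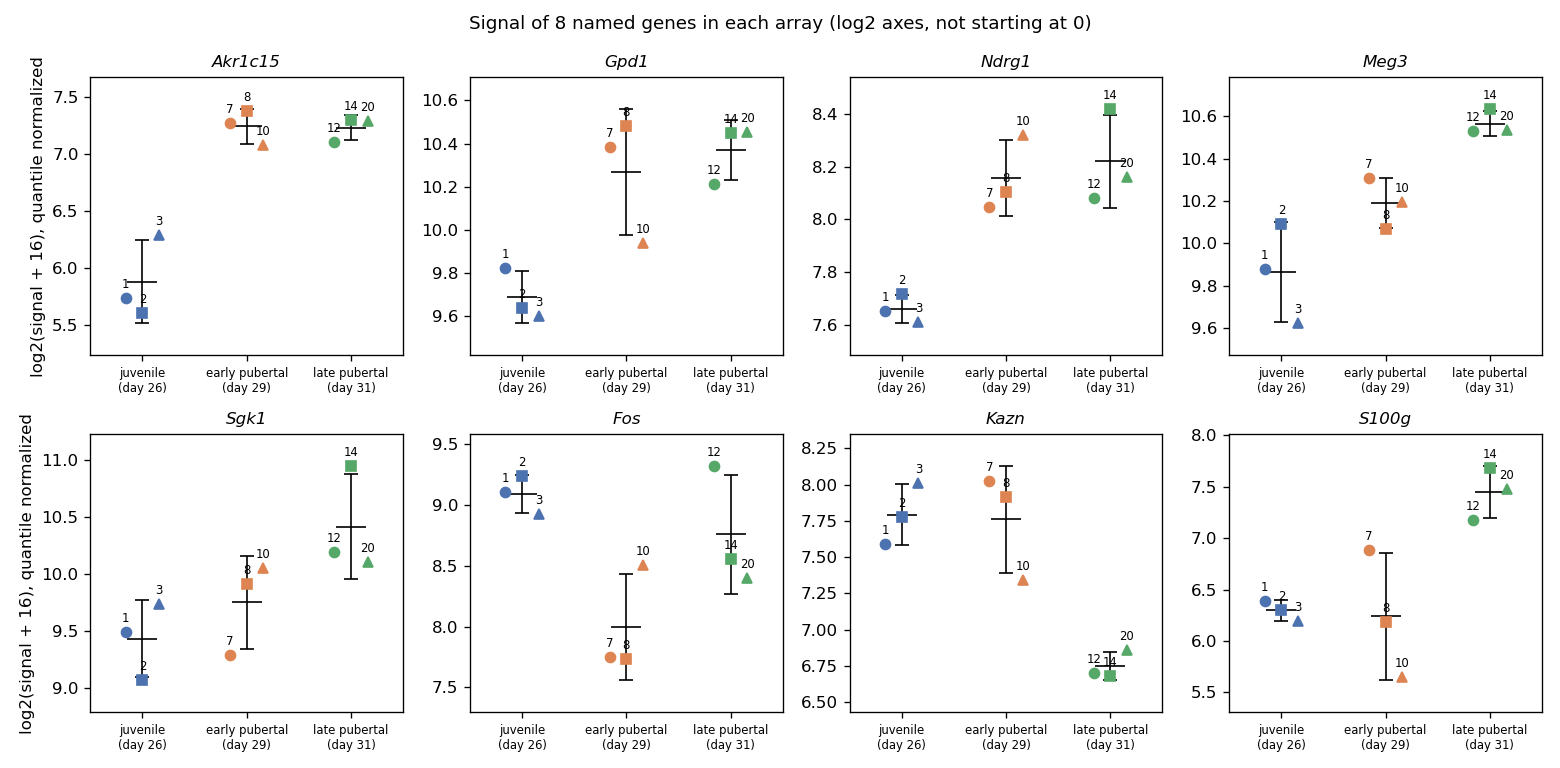
Quantile-normalized log2(signal + 16) of Akr1c15, Gpd1, Ndrg1, Meg3, Sgk1, Fos, Kazn and S100g in the hypothalamus of juvenile, early pubertal and late pubertal rats, with each array a point numbered by its replicate, horizontal bars for group means, error bars for the SD (n = 3) and vertical axes that do not start from 0. Akr1c15 lay at a mean of 5.88 in juvenile, 7.24 in early pubertal and 7.23 in late pubertal animals and Fos in early pubertal animals lay at a log2 difference of −1.10 from juvenile.

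Camera called 5 of 30 lists between these stages, all higher in late pubertal animals, while 0 passed with an estimated correlation and 0 by fry. With each array centred on its median the split was 5 higher and 2 lower. Without juvenile replicate 2 it was 4 and 4, and without late pubertal replicate 14 only 3 lists passed, all higher. Glucocorticoid-responsive genes were higher for 12 of 16 members, by 0.30 relative to other genes (camera adjusted p 2.15e-07, and adjusted p = 0.301 with an estimated correlation). No member passed over all genes, and 7 of 16 passed when adjusted over the list alone. Sgk1, a kinase that corticosteroids induce, differed by 0.98 ± 0.25 (SE, n = 3 per stage), Klf9, a transcription factor that glucocorticoids induce, by 0.35 ± 0.09, Arrdc2 by 0.66 ± 0.20 and Fkbp5 by 0.36 ± 0.11, or by 0.11 on its other probe set. The call held without any single array, at adjusted p up to 0.00224. Markers of leptomeninges and fibroblasts were higher in the same stage for all 15 members, by 0.25 (camera adjusted p 2.15e-07, and adjusted p = 0.365 with an estimated correlation), with 0 passing over all genes or when adjusted over the list alone. Fmod, the proteoglycan fibromodulin, differed by 0.40 ± 0.12, Dcn by 0.41 ± 0.15, Mgp by 0.36 ± 0.14 and Slc6a13 by 0.43 ± 0.20. This call too held without any single array, at a camera adjusted p up to 0.000223. For both lists these fits kept the preset correlation of 0.01, while the estimated correlation was 0.506 for leptomeninges and 0.114 for glucocorticoid-responsive genes. Per array, late pubertal replicate 14 was high in both lists (glucocorticoid score 0.28, leptomeninges score 0.24), as was early pubertal replicate 10 (0.23 and 0.37). Late pubertal replicate 12 had 0.15 and −0.0230, and replicate 20 had 0.01 and 0.13. Juvenile replicates 1, 2 and 3 had glucocorticoid scores of −0.12, −0.26 and −0.09 and leptomeninges scores of −0.18, −0.0196 and −0.19. The leptomeninges scores of juvenile and late pubertal arrays thus overlapped.

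Cytosolic ribosomal proteins were higher for 26 of 31 members in late pubertal animals, by 0.06 (camera adjusted p 5.18e-05, and adjusted p = 0.301 with an estimated correlation), with Rplp0 at 0.17 ± 0.07 and Rps3a at 0.11 ± 0.05. Without normalization between arrays the ribosomal shift was 0.08. Astrocyte markers were higher for 10 of 16 members, by 0.07 (camera adjusted p 0.0320, and adjusted p = 0.421 with an estimated correlation), with Ntsr2 at 0.16 ± 0.06, the connexin Gjb6 at 0.27 ± 0.09 and Aldh1l1 at 0.31 ± 0.11. Choroid plexus markers were higher for 7 of 9 members, by 0.20 (camera adjusted p 0.0339, and adjusted p = 0.301 with an estimated correlation), with the growth factor Igf2 at 0.25 ± 0.12, Col8a1 at 0.55 ± 0.27 and Igfbp2 at 0.25 ± 0.15. In these 3 lists 0 members passed over all genes or when adjusted over the list alone. The astrocyte call was lost without juvenile replicate 2 (shift 0.01, adjusted p 0.665), late pubertal replicate 14 (0.03, 0.119) or late pubertal replicate 20 (0.135), and its shift was 0.04 (adjusted p 0.0857) on the mean of each gene's probe sets. It was lost without trend (0.124) and with array weights (0.254). The choroid plexus call was lost without juvenile replicate 1 (0.0739) or 3 (0.0541) or late pubertal replicate 14 (0.104), without the signal filter (shift 0.04, adjusted p 0.638), without trend (0.124), on the mean of each gene's probe sets (0.0555) and without genes that other lists hold (0.0742).

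The GnRH control list was higher for 11 of 16 members in late pubertal animals, by 0.06 relative to other genes, at a camera adjusted p of 0.317, with 0 members passing over all genes or when adjusted over the list alone. Npvf had a value of 0.60 ± 0.23 (SE, n = 3 per stage), Pdyn one of 0.29 ± 0.13 and Cartpt, which encodes an anorexigenic peptide, one of 0.18 ± 0.09. Immediate early genes stood near juvenile levels as a list, with a mean of −0.02 relative to other genes, 7 of 16 higher and a camera adjusted p of 0.636. Without normalization between arrays that mean was −0.06.

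**Figure D2:**
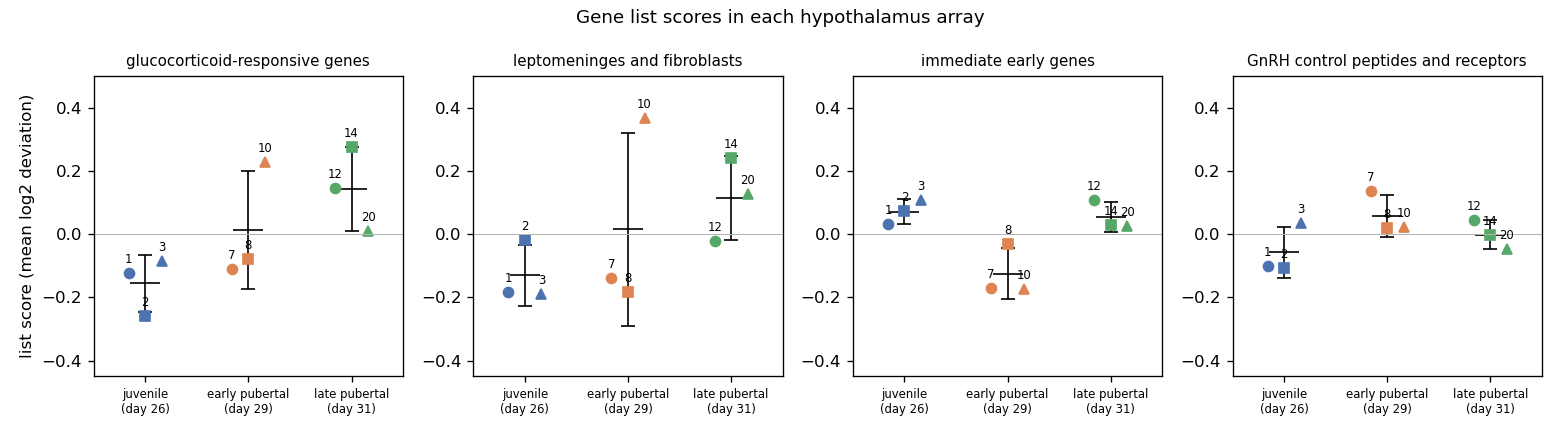
Mean log2 deviation of the members of the glucocorticoid-responsive, leptomeninges and fibroblast, immediate early and GnRH control lists from their average over the 9 arrays, relative to all tested genes, with each array a point numbered by its replicate, horizontal bars for group means and error bars for the SD (n = 3). Glucocorticoid scores averaged −0.16 in juvenile, 0.01 in early pubertal and 0.14 in late pubertal animals, and early pubertal replicate 10 stood at 0.23 in that list and at 0.37 in the leptomeninges list.

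The comparison of day 31 with day 29 asked what separates late from early puberty. S100g, the vitamin D-dependent calcium-binding protein calbindin-D9k, stood 1.21 ± 0.27 (SE, n = 3 per stage) higher on the log2 scale in late pubertal animals, and also 1.15 ± 0.27 above juvenile. Tcap, a protein of the muscle sarcomere, stood 1.28 ± 0.29 higher, Rad18, a ubiquitin ligase of DNA damage tolerance, 0.60 ± 0.14 and Hhipl1 0.82 ± 0.19, with its other probe set at 0.03. S100g, Tcap and Hhipl1 were dim in early pubertal animals, at mean log2 levels of 6.24, 6.07 and 5.97. Kcnt1, a sodium-activated potassium channel, stood 0.53 ± 0.12 higher on the named probe set, with the other two at −0.02 and −0.36. Kazn differed by −1.01 ± 0.19, with its other probe sets at −0.26 and 0.17, Cyb561d2 by −0.71 ± 0.13 and the heparan sulfate editing enzyme Sulf1 by −0.71 ± 0.16. Tnfrsf21, a death receptor, differed by −0.68 ± 0.16, or by −0.27 on its other probe set, and the acetyltransferase Naa30 by −0.53 ± 0.12, with the other Naa30 probe set at 0.04. By the naming rule, the stages did not overlap for these genes, and each had a limma adjusted p of 0.914. Limma with Benjamini-Hochberg adjustment called 0 of 18625 probe sets, while 971 had an unadjusted p under 0.05, 548 higher and 423 lower, and 1112 higher and 1000 lower were fully separated, 11.3% against 10% by chance. Without normalization between arrays it called 21 probe sets, all 21 higher, beside a median difference of 0.22, among them those of Tcap (adjusted p 0.00997), S100g (0.0293) and Fos (0.0394).

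Camera called 0 of 30 lists between early and late puberty at an adjusted p under 0.05, with 6 at an unadjusted p under 0.05, 0 with an estimated correlation and 0 by fry. Immediate early genes were higher for 12 of 16 members, by 0.18 relative to other genes (camera adjusted p 0.0964, and adjusted p = 0.526 with an estimated correlation), with 0 passing over all genes or when adjusted over the list alone. Fos stood 0.76 ± 0.24 (SE, n = 3 per stage) higher, Ier2 0.46 ± 0.15, Egr1 0.44 ± 0.16 and Egr4 0.66 ± 0.34. Glucocorticoid-responsive genes were higher for 11 of 16 members, by 0.13 (camera adjusted p 0.249), with Sgk1 at 0.66 ± 0.25, Per1 at 0.85 ± 0.43 and the metallothionein Mt2A at −0.33 ± 0.14. Klf9 stood 0.26 ± 0.09 higher, and its other probe set gave −0.02. In the GnRH control list 7 of 16 members were higher, with a mean of −0.06 (camera adjusted p 0.403), Nts at −0.33 ± 0.12, Tac3 at −0.35 ± 0.17 and Pgr at 0.45 ± 0.21. Among the puberty-linked regulators, with a mean of 0.06 and a camera adjusted p of 0.485, 6 of 9 members were higher, and Irf2bpl stood at 0.19 ± 0.07 and Nkx2-1, a homeobox gene of hypothalamic development, at −0.20 ± 0.12. In these 3 lists 0 members passed over all genes or when adjusted over the list alone. The count of lists depended on single arrays and on scaling: it was 1 without juvenile replicate 1 or early pubertal replicate 7, 2 without early pubertal replicate 10 or late pubertal replicate 14, and 3 without early pubertal replicate 8 or late pubertal replicate 20. Without normalization between arrays 4 lists were higher and 2 lower, and with each array centred on its median 1 was higher and 3 lower.

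A single test over all 3 stages asked whether any transcript varied at all. Limma's moderated F test with Benjamini-Hochberg adjustment called 0 of 18625 probe sets, with 786 at an unadjusted p under 0.05 and a smallest adjusted p of 0.319, that of Akr1c15. The count was 1 without juvenile replicate 2 and 16 without normalization between arrays. Hhipl1 and Dnajc7, low in early pubertal animals, stood at −0.29 ± 0.19 and −0.19 ± 0.30 (SE, n = 3 per stage) against juvenile in late pubertal animals, with other probe sets of both genes at 0.23 and 0.01, and Cyb561d2 stood at −0.36 ± 0.13. Across probe sets, which are not independent replicates, the early and late pubertal differences from juvenile correlated at r = 0.428, with a covariance of 0.0135. Because both differences use the same 3 juvenile arrays, unchanged groups simulated against those arrays gave a mean r of 0.477, from −0.478 to 0.993, with r as high in 58 of 100 simulations and a mean covariance of 0.0166. Both observed values thus lay within the range that shared controls gave with no effect, and the juvenile arrays are too few to be split.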

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

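The lists without genes that other lists hold and the immediate early list without Fos were tests chosen only after the result was seen. Of 2752 alternative values of 147 named-gene results, 2742 kept their direction and side of the threshold, 9 came to pass it and 1 reversed. None of these results passed in the main setting, so keeping the side means still not passing. Many of the genes were also picked on these arrays by small p or non-overlap. The count is therefore no measure of how firm the differences are. Of 289 alternatives for the 12 called lists, 223 kept the call, 65 lost it and 1 reversed. The reversals were Usf2 in late pubertal against juvenile animals, at −0.000471 without juvenile replicate 2 (range over arrays left out −0.000471 to 0.471), and the leptomeninges list in early pubertal against juvenile animals, at −0.0316 without early pubertal replicate 10 (range −0.0316 to 0.244). Both come from dropping a single array, and the cause was not tested. At the deposited level, 10, 1 and 21 probe sets passed for early against juvenile, late against juvenile and late against early, and 16 in the F test, where the normalized values gave 0, and 6 lists passed for late against early. Between early and late puberty, where 0 lists passed, 4 did with median centring, 3 with the filter at the 60th percentile, 2 with the mean of a gene's probe sets and 1 at a threshold of 0.1. A prior without trend left 3 lists for early and 3 for late against juvenile, in place of 7 and 5. With only the 6 arrays compared 8 lists passed for late against juvenile, and 9 at a threshold of 0.1. Array weights called 1 probe set there. An estimated correlation left 0 lists for both comparisons with juvenile, and fry 0. Except for the looser threshold, which admits more by construction, the causes were not tested. Over arrays left out, 1 to 8 lists passed for early against juvenile, 3 to 8 for late against juvenile and 0 to 3 for late against early, 0 to 1 probe sets for late against juvenile, 0 to 1 in the F test and 0 in the other comparisons. The correlation of the differences from juvenile ran from 0.335 to 0.588. No paired analysis was possible because the stages share no replicate numbers. The number of arrays, 3 per stage, limits the precision.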

Other observations

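The tests of list scores by exact permutation, of the immediate early list without Fos, of clock genes and of the correlation among leptomeningeal genes were chosen only after the result was seen. The following list values did not pass camera with Benjamini-Hochberg adjustment, and no member passed limma over all genes. In late pubertal against juvenile animals, markers of neurons were lower for 14 of 18 members, by a mean of −0.07 relative to other genes (adjusted p 0.0632), with the synaptic vesicle proteins Syt1 at −0.42 ± 0.15 (SE, n = 3 per stage), Vamp2 at −0.26 ± 0.11 and Syn1 at −0.23 ± 0.09. Syn2, also of synaptic vesicles, went the other way at 0.20 on the named probe set, while its other probe sets gave −0.05 and −0.40. GABA signalling genes were lower for 14 of 19, with a mean of −0.08 (adjusted p 0.0619), and 1 passed when adjusted over the list alone: Slc32a1, the vesicular GABA transporter, at −0.40 ± 0.10 (0.0406). Markers of immature neurons were lower for 14 of 18, with a mean of −0.08 (adjusted p 0.0529), and heat shock and unfolded protein genes for 16 of 19, with a mean of −0.06 (adjusted p 0.0690). Between early and late puberty the endoplasmic reticulum chaperones Calr and Hsp90b1 had values of −0.31 ± 0.09 and −0.20 ± 0.08 in a list shifted by −0.06 (adjusted p 0.126). Microglial markers were lower in late than early puberty for 11 of 16, with a mean of −0.10 (adjusted p 0.126), with the complement gene C1qb at −0.60 ± 0.15, which passed when adjusted over the list alone (0.0273), and Csf1r at −0.25 ± 0.10. Pituitary markers were lower for 6 of 7, with a mean of −0.24 (adjusted p 0.132), with Trhr at −0.27 ± 0.11 and Lhb at −0.29 ± 0.14.

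In early pubertal against juvenile animals, cholesterol synthesis genes had a mean of 0.05 (adjusted p 0.212), with Fdps, farnesyl diphosphate synthase, at 0.29 ± 0.07 and passing when adjusted over the list alone (0.0390). Markers of oligodendrocytes and myelin were higher for 16 of 21, by 0.07, those of ependyma and tanycytes for 8 of 12, by 0.10, and oxidative phosphorylation genes for 34 of 51, by 0.04, each at an adjusted p of 0.127. Without normalization between arrays the oxidative phosphorylation shift was 0.07. Oligodendrocyte precursor markers were lower for 7 of 8, with a mean of −0.07 (0.208), thalamic markers for 8 of 10, with a mean of −0.08 (0.252), and glutamate signalling genes for 18 of 30, with a mean of −0.03 (0.590). For GABA signalling in this comparison the mean was 0.01, while the median was −0.06 and the test pointed down (0.491). Striatal markers stood at 0.04 (0.461) and cortical and hippocampal markers at 0.08 (0.671), the latter at −0.01 without normalization between arrays. In late pubertal against juvenile animals, other hypothalamic neuropeptides stood at −0.07 (0.209), glial growth factor and adhesion genes at −0.06 (0.156), circadian clock genes at 0.06 (0.235) and cell cycle genes at 0.05 (0.844). In late against early puberty, endothelial and mural markers stood at −0.05 (0.471), tumor suppressor and DNA damage genes at 0.05 (0.613) and other puberty-timing regulators at 0.02 (0.829).

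The score of each list per array was also compared over the 280 splits of the 9 arrays into 3 stages. Immediate early genes gave an exact p of 0.0179, heat shock genes 0.0607, glucocorticoid-responsive genes 0.0714, immature neurons 0.0750 and thalamic markers 0.0786, and after Benjamini-Hochberg adjustment over 30 lists each stood at 0.471. Among the other lists that camera called, the exact p was 0.154 for ribosomal proteins, 0.196 for GnRH control and 0.214 for choroid plexus. For leptomeninges it was 0.396 (adjusted 0.857) and for astrocytes 0.536 (adjusted 0.862). The permutation of array scores thus called none of the lists that camera called. With 280 splits, however, a single list at the smallest possible exact p would not pass adjustment over 30 lists. The lack of calls was therefore nearly fixed in advance and does not count against the camera calls.

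The glucocorticoid-responsive list was 0.299 higher per array in late pubertal than in juvenile animals. With array brightness as a covariate the shift was 0.311 ± 0.0706 (SE), which argues against brightness as the whole cause. With the beta-actin ratio as a measure of RNA integrity it was 0.303 ± 0.124, which met the rule set beforehand against that cause. Because that SE is wide, a part played by RNA integrity stays open. With the leptomeninges score as a covariate the shift was 0.187 ± 0.114, too imprecise to settle whether meningeal tissue carried along may contribute. A different time of day at dissection is a candidate explanation that stays open. Among the clock genes Bmal1, Dbp, Nr1d1 and Per2 the smallest unadjusted p in limma was 0.0274, for Bmal1 at −0.34 ± 0.13. This met the criterion of any of the 4 genes under 0.05, which was itself set after the data were seen. Adjusted over the 4 genes, a form tried after the values were seen, the limma p was 0.0973. Dbp stood at 0.27 ± 0.13, Nr1d1 at −0.24 ± 0.12 and Per2 at 0.22 ± 0.15. The difference in age and stage itself remains open and untested, and 3 of the 16 genes belong to other lists too.

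The immediate early list shifted by −0.196 per array from juvenile to early pubertal animals. With array brightness as a covariate the shift was −0.217 ± 0.0685 (SE). Median signal did not overlap between these stages, at 102 to 113 in juvenile and 79.8 to 101 in early pubertal arrays. The covariate therefore cannot separate brightness from stage, and brightness stays open as a cause. Without Fos the shift was −0.136 ± 0.0543, more than 2 SE from 0, and camera still called the list (adjusted p 0.0182), which argues against Fos as the whole cause. Whether Fos could make up most of the shift stays open, because the remaining shift is too imprecise. These genes respond within minutes to handling and arousal, for which the labels hold no measure, and the difference in stage was not tested apart from it.

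The leptomeninges and fibroblast list was 0.245 higher per array in late pubertal than in juvenile animals. Within stages its members rose and fell together from animal to animal, with a mean correlation of 0.506 where 1000 random lists had a 95th percentile of 0.106, but 7 of the 29 other lists also lay above that percentile, up to 0.382 for oligodendrocytes and myelin, so the test leaves open whether the amount of membrane left on the dissected tissue varied. Of its most abundant genes, Ptgds stood at a log2 level of 13.05 in juvenile and 13.11 in late pubertal animals (difference 0.06 ± 0.04), Igf2 at 11.60 and 11.86 (0.25 ± 0.12) and Col1a2 at 10.94 and 11.10 (0.16 ± 0.16). All 15 members passed the signal filter in this tissue and 2 belong to other lists, and no sort was made that would remove such cells. With brightness as a covariate the shift was 0.255 ± 0.153 (SE), too imprecise to exclude it, and a change of the membranes with stage stays open and untested.

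Other splits of the same arrays bear on the counts. The 6 arrays of a pairwise comparison make only 10 splits, too few for a share under 0.05, and where the real count is 0 every split reaches it. For probe sets 10 of 10 splits gave as many calls as the real count of 0 in each pairwise comparison, with highest other counts of 0 for early against juvenile, 1 for late against juvenile and 5 for late against early. For lists, 2 of 10 splits gave as many as the real 7 for early against juvenile, where the highest other was 7, and 3 of 10 as many as the real 5 for late against juvenile, where it was 5. For late against early 10 of 10 splits gave as many lists as the real 0, with 7 as the highest other. In the F test 100 of 100 splits gave as many probe sets as the real 0, with 4 as the highest other, which settles nothing about chance because no split can give fewer.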
